A study of Rattus norvegicus with 4 samples.

How the data were processed

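The series holds 4 chromatin immunoprecipitation (ChIP-seq) libraries from rat nucleus pulposus cells, the cells of the soft centre of the intervertebral disc. Per the labels' protocols, the cells were grown in medium with 10% fetal bovine serum or were serum-starved in 0.1% serum. Each condition has 1 library precipitated with an antibody against CD44, the cell-surface receptor for hyaluronan, and 1 input library of DNA that was not precipitated. Libraries were made from DNA purified with phenol and chloroform, selected for fragment size and sequenced in paired-end mode, per the labels' protocols.

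The authors deposited 1 peak list per condition, and these 2 lists are the data used here. Per the submitters' processing notes, the build is Rnor_6.0 and the tools named are FastQC, STAR 2.5.3a and MACS2 2.1.1. The options given to these tools, the handling of duplicate reads and the scaling of one library to another are not given in the sources used here. The peak names in each list carry the prefix of that condition's library titles, which placed each list with its immunoprecipitation. Each row of the deposited lists gives a peak's position, its length, a fold enrichment, an uncorrected p-value, a q-value named FDR in the file headers, and a pileup signal. The fold enrichment is a ratio of peak height to local background with 1 added to both. At a background well below 1 it therefore lies far under the plain ratio. The pileup signal is the number of fragments stacked at the peak's highest point. All these values are the authors' own and describe a peak within its list. Positions were 1-based, since the length equalled end minus start plus 1 in all 289279 serum and 409937 starved peaks. No peak overlapped another of the same list. The largest p-value was 0.04997 in the serum list and 0.04972 in the starved list.

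The local background of each peak was computed from the deposited values as (pileup + 1) divided by the fold enrichment, minus 1. With this background, the Poisson probability of a pileup above the one listed matched the deposited p-value within 0.05 on the log10 scale for 100% of the peaks of both lists. The lowest background of a list stands for its genome-wide fragment density as the peak caller used it. A peak was counted as at the lowest background when its own was at most 1.01 times the lowest of its list, and as having a raised background when it was more than 2 times the lowest. Read totals were not used here. The lowest background and the pileups give the depth relative to each other only, after any scaling by the authors.

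Peaks of the 2 lists were called shared when they overlapped by at least 1 bp. The overlap expected by chance came from 100 seeded placements of one list at random positions of the same sequence, and from 100 seeded placements in which each peak was moved by 10 to 100 kb, which keeps the regional density. The last peak end of either list stood in for the length of a sequence. Random positions can fall in assembly gaps, which lowers the expected overlap. Peak densities per Mb were computed for chromosomes 1 to 20, X and Y. Intervals are exact 95% binomial intervals for shares and exact 95% Poisson intervals for densities. They cover counting error only, and neighbouring peaks are not independent. With 1 immunoprecipitated library per condition there is no replicate check on any difference between conditions. No p-value between conditions is therefore given, and every difference describes these libraries.

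The overlap and background calculations were tested on simulated data before use. All 3000 simulated peaks with a known partner were found (100%), and 0 of 7000 peaks without one were called overlapping. Random placement of 10000 simulated peaks gave an overlap of 5.98% where 5.99% was calculated. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with bedtools 2.31.1 for overlaps and matplotlib 3.10.9 for plots.

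The comparisons, the alternatives, 15 gene lists, 14 sequence motifs and the rule for named genes were fixed before the data were examined. The rule would have named the CD44 gene, the leading promoter peaks of each list and the genes nearest the strongest peaks. A genome and gene annotation of Rnor_6.0 were not used here, and coordinates were not carried between builds. Peaks were therefore not assigned to genes, promoters, exons or introns, so the gene lists, motifs, base composition and named genes were not analysed here. The comparisons that remained are the peak numbers, the overlap, the distribution over chromosomes and the strongest peaks. Alternatives were stricter q-values, a stricter overlap, nearness within 500 bp, lists of equal length, and numbered chromosomes and X only. The chance overlap from moved peaks, the limit of 2 times the lowest background, the q-value limit of 0.05 and the windows of 1 Mb, 2 Mb and 10 Mb were chosen after seeing the data. Single peaks named for having no counterpart, the mitochondrial peaks and the named windows were also chosen after their values were seen.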

Results

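CD44 ChIP-seq peaks were compared between rat nucleus pulposus cells kept in 10% serum and cells starved in 0.1% serum, with 1 immunoprecipitated library per condition and its input. The comparison asks where on the genome DNA was recovered with an antibody against CD44, and whether these places differ after serum withdrawal. CD44 is a membrane receptor for hyaluronan. Its cut intracellular part has been described in the nucleus. The serum list held 289279 peaks that covered 117 Mb, and the starved list held 409937 peaks that covered 126 Mb. All positions are on Rnor_6.0, and the annotation of genes on that build was not used here.

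The depth behind the lists differed. The lowest local background was 1.502 stacked fragments in the serum list and 0.0996 in the starved list, a 15.1-fold difference. The shortest peaks were 272 bp in the serum list and 217 bp in the starved list. If these lengths are taken as the fragment lengths, the serum list rested on 12.0 times as many fragments per unit of genome, after any scaling in peak calling. The median pileup was 7 fragments in serum peaks and 2 fragments in starved peaks. A pileup of 1 fragment was enough for a peak in the starved list, and 167525 of its peaks (40.9%) had that height. The lowest pileup in the serum list was 4.

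Most serum peaks were weak. Only 57574 of them (19.9%, 95% interval 19.76 to 20.05) had a q of at most 0.05, against 213064 starved peaks (52.0%, interval 51.8 to 52.1). At a −log10 q of at least 5 the lists held 3539 serum and 53117 starved peaks, so that the ratio of starved to serum peaks went from 1.42 over all peaks to 15.0 at this limit. The same q rested on fewer fragments in the starved list. At the lowest background, a q of at most 0.05 took at least 8 fragments in the serum and 2 in the starved list. At a −log10 q of at least 5, the median pileup was 29 in shared and 15 in unshared serum peaks. For starved peaks at this limit it was 9 and 7. These differences between the lists have no replicate behind them, and the lists differ in depth as given above.

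**Figure D1:**
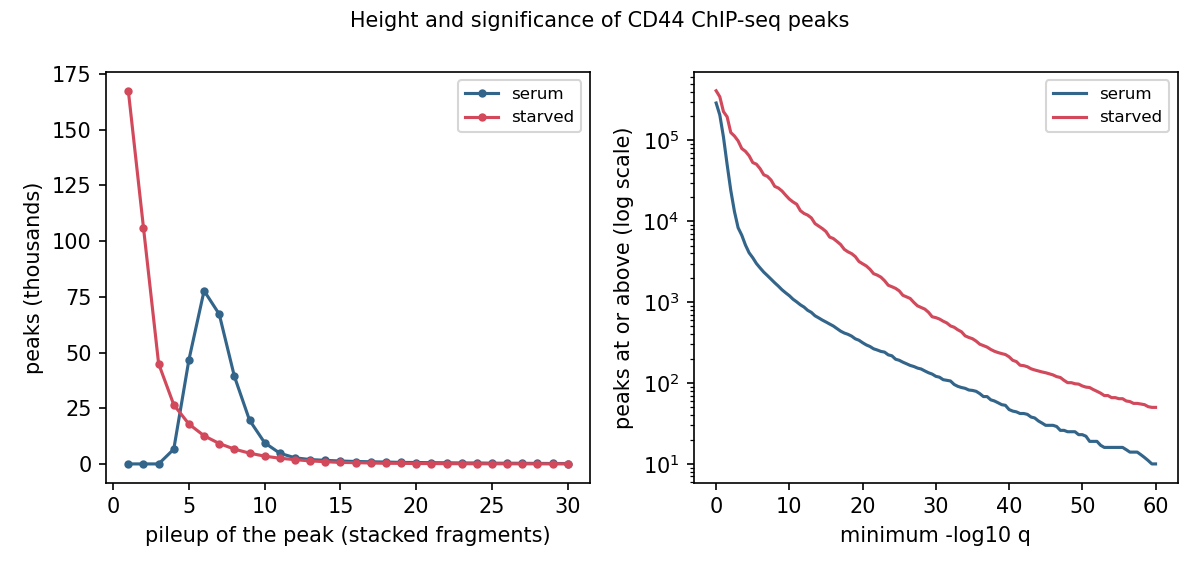
Left, number of peaks by pileup in stacked fragments, and right, number of peaks at or above each −log10 q (log scale), for the serum list (blue) and the starved list (red), 1 immunoprecipitated library each. Serum pileups start at 4 and starved pileups at 1, and at a −log10 q of 5 the curves stand at 3539 and 53117 peaks.

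The strong serum peaks were nearly all found again in starved cells, while most strong starved peaks had no serum counterpart. Of the 1200 serum peaks with a −log10 q of at least 10, 1168 (97.3%) overlapped a starved peak. Of the 315 at 20 or more, 304 did (96.5%, interval 93.8 to 98.2), and peaks moved by 10 to 100 kb did so in 14.0%. Of the 2980 starved peaks at 20 or more, 1072 (36.0%, interval 34.2 to 37.7) overlapped a serum peak, against 11.4% for moved peaks. Over all peaks, 45508 serum peaks (15.7%, interval 15.6 to 15.9) and 45105 starved peaks (11.0%, interval 10.9 to 11.1) were shared. Random placement gave 10.1% for serum and 7.23% for starved peaks.

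The shared part was larger among stronger peaks in both lists. In the serum list it was 12.7% at a q above 0.05, 20.9% at a −log10 q of 1.3 to 3, 56.2% from 3 to 5, 86.7% from 5 to 10 and 97.6% from 10 to 20. In the starved list the same classes gave 7.67%, 10.4%, 14.7%, 19.7% and 23.0%. Among the 315 serum peaks at 20 or more, 293 (93.0%) overlapped a starved peak that itself had a −log10 q of at least 5. In the other direction, 694 of the 2980 starved peaks at 20 or more (23.3%) overlapped a serum peak with a −log10 q of at least 5. At that limit the lists held 53117 starved and 3539 serum peaks, so these shares depend on list size. With both lists at 20 or more, the numbers of overlapping peaks were nearly equal. They were 193 of 315 serum peaks (61.3%) and 192 of 2980 starved peaks (6.44%).

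**Figure D2:**
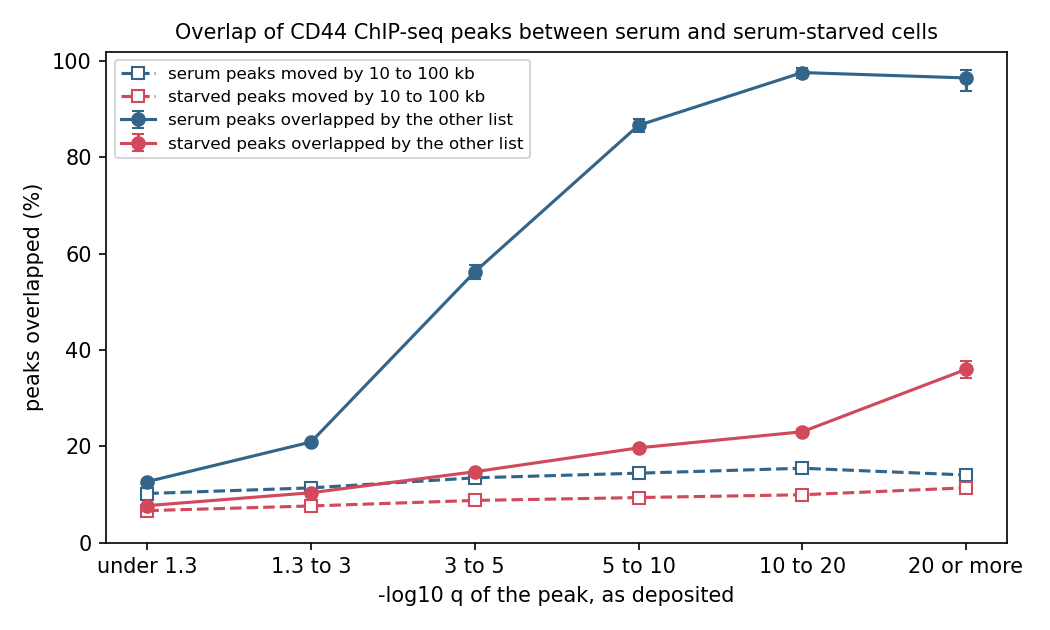
Share of peaks overlapped by the other list (%) by class of −log10 q, for serum peaks (blue) and starved peaks (red); filled circles are observed shares with exact 95% binomial intervals and open squares are the means of 100 sets of peaks moved by 10 to 100 kb. Serum peaks go from 12.7% to 97.6% and end at 96.5%, and starved peaks go from 7.67% to 36.0%, while moved serum peaks reach 15.4% at most and moved starved peaks 11.4%.

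Weak peaks at a low background were shared only slightly more often than moved peaks, 1.02 times as often in the serum and 1.09 times in the starved list. Serum peaks with a background of up to 2 times the lowest and a q above 0.05, 214801 in number, were shared in 10.2%, against 10.1% for the same peaks moved. Starved peaks of this kind, 137249 in number, were shared in 7.26% (interval 7.12 to 7.39), against 6.67% when moved. Peaks of any strength at the lowest background were shared in 9.47% in the serum list, against 10.6% when moved, and in 9.79% in the starved list, against 8.74% when moved. Serum peaks with a background more than 5 times the lowest were shared in 78.9% (interval 77.64 to 80.03). Strong serum peaks at −log10 q of at least 5 and a background of up to 2 times the lowest were few, 894, and 679 of them (76.0%, interval 73.0 to 78.7) were shared, against 14.3% when moved.

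Shared starved peaks were longer and more often of raised background than unshared ones. Among starved peaks with a −log10 q of at least 20, the median length was 697 bp for shared peaks (quartiles 418 and 1287 bp) and 365 bp for unshared peaks (quartiles 322 and 414 bp). A raised background held for 69.0% of the shared and 10.4% of the unshared ones, and at a −log10 q of at least 5 for 57.1% and 18.2%. Of the 4032 starved peaks at −log10 q of at least 5 that were 1 kb or longer, 3228 (80.1%, interval 78.8 to 81.3) were shared, against 22.3% when moved. Of the 49085 shorter ones, 8235 (16.8%) were shared, against 8.60% when moved.

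All 10 serum peaks with the highest fold enrichment overlapped a starved peak. The highest, 39.6-fold, lay on an unplaced scaffold, where the starved list had a 56.4-fold peak. The next were on chromosome 13 from 80784245 to 80784845 (22.0-fold), chromosome 5 from 37622161 to 37622565 (19.4-fold), chromosome 14 from 29152966 to 29153866 (18.2-fold) and chromosome 2 from 77632159 to 77632642 (17.9-fold). Within the starved list the overlapping peaks had fold enrichments of 45.5, 20.1, 9.82 and 44.8. A serum peak of 4820 bp on chromosome 6 from 30402629 to 30407448 (16.0-fold) was the longest of the 10. Fold enrichments of different lists rest on different backgrounds and are not compared here.

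Of the 10 starved peaks with the highest fold enrichment, 6 overlapped a serum peak and 4 did not. The 4 without one lay on chromosome 8 from 109261811 to 109262228 (68.2-fold, pileup 74), chromosome 2 from 162972378 to 162973000 (59.1-fold, pileup 64), chromosome 15 from 21192484 to 21192870 (49.1-fold, pileup 56) and chromosome 17 from 39640160 to 39640541 (47.3-fold, pileup 51). The shared ones included chromosome 10 from 48880972 to 48881895 (67.0-fold), chromosome 10 from 63884048 to 63884698 (47.5-fold) and chromosome 2 from 77586517 to 77587236 (43.9-fold). In the serum list, 11 peaks with a −log10 q of at least 20 had no starved counterpart, and all 11 had a raised background. The first of these lay on chromosome 15 from 22211620 to 22212078, with a fold enrichment of 4.26 on a background 20.3 times the lowest.

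Several 1 Mb stretches held many strong peaks in both lists. Chromosome 9 from 4000001 to 5000000 held 75 serum and 52 starved peaks with a −log10 q of at least 5. Chromosome 1 from 63000001 to 64000000 held 12 serum and 56 starved peaks, and chromosome 1 from 180000001 to 181000000 held 17 and 54. Chromosome 13 from 33000001 to 34000000 held 15 and 48, while chromosome 3 from 75000001 to 76000000 held 5 serum and 48 starved peaks. The median background of the serum peaks was 26.4 times the lowest in the chromosome 1 stretch that starts at 180000001 and 35.1 times in the chromosome 13 stretch, but 2.86 times in the chromosome 9 stretch.

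Serum peaks were spread unevenly over the chromosomes and starved peaks nearly evenly. In the serum list the density ran from 43.0 peaks per Mb on chromosome 4 (interval 42.1 to 44.0) to 179 on X (interval 177 to 181), a 4.16-fold range over 21 chromosomes with a median of 107. Chromosomes 10 (53.5 per Mb) and 12 (49.4 per Mb) were also low. Chromosome 10 was not low along its whole length. Its 10 Mb windows held 587 to 1167 serum peaks up to 60 Mb, and 87 to 321 beyond it. In the starved list the density on these chromosomes ran from 135 peaks per Mb on chromosome 12 to 155 on X, a 1.14-fold range, and chromosome 4 stood at 145. The starved range was wider at a q of at most 0.05 (1.32-fold), at a −log10 q of at least 5 (1.39-fold) and at a background of up to 2 times the lowest (1.74-fold). The serum ranges at these settings were 4.32-fold, 2.81-fold and 5.05-fold. At a −log10 q of at least 5 the serum density on chromosome 4 was 0.942 times that of all chromosomes, against 0.416 times over all peaks. Chromosomes 10 and 12 stayed lower at this limit, at 0.612 and 0.583 times, and X was 1.63 times as dense.

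The local background also differed between chromosomes, in the same way in both lists. On chromosome 4, 4.56% of serum and 2.90% of starved peaks were at the lowest background of their list, and on X 74.2% and 57.6% were. Chromosome 20 came next to X, with 47.7% and 31.5%. The median background on chromosome 4 was 1.33 times the median of the other autosomes in the serum list and 1.36 times in the starved list. Over the 21 chromosomes, the share of peaks at the lowest background had a Spearman rho of 0.958 between the lists, and 0.952 over the 20 autosomes. Chromosomes are not independent replicates, so this describes the libraries.

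**Figure D3:**
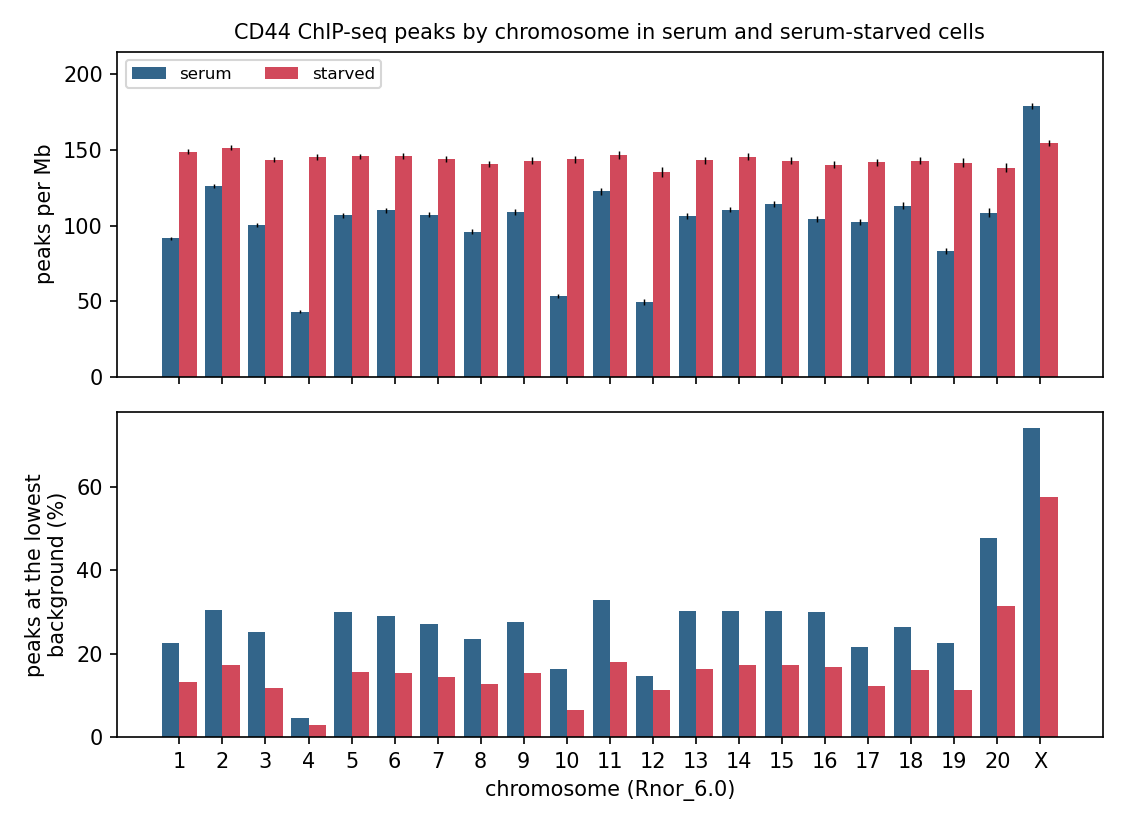
Top, peaks per Mb on chromosomes 1 to 20 and X in the serum list (blue) and the starved list (red), with exact 95% Poisson intervals as black lines. Bottom, share of each of these chromosomes' peaks (%) at the lowest local background of its list. Serum density is 43.0 per Mb on chromosome 4 and 179 on X while starved density stays between 135 and 155, and the bottom panel has its lowest bars on chromosome 4 and its highest on X in both lists.

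The Y chromosome had 87 serum and 432 starved peaks. The mitochondrial genome had 0 serum and 3 starved peaks, at positions 816 to 1042, 2374 to 2619 and 7154 to 7486. Their fold enrichments were 3.11, 2.33 and 2.16 on a background at least 67.4 times the lowest. Unplaced scaffolds held 0.548% of serum and 1.38% of starved peaks.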

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

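All tests in this part were chosen after the data had been seen; for that of a regional trend, that of the starved background under low-background serum peaks and that of the 10 Mb windows of chromosome 4, the limit was set before the value was computed. For 8 chromosomes the peak density relative to all chromosomes lay on opposite sides of the average in the 2 lists, a difference that was not tested and that has no replicate. The log2 values in the serum list were −0.18 for chromosome 1, 0.048 for chromosome 7, 0.072 for chromosome 9, 0.036 for chromosome 13, 0.14 for chromosome 15, 0.013 for chromosome 16, 0.13 for chromosome 18 and 0.068 for chromosome 20. The starved values for the same chromosomes lay between −0.074 and 0.035.

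Strong starved peaks without a serum peak numbered 1908 at a −log10 q of at least 20. The lists argue against too few serum reads as the source of these peaks. With the shortest peak lengths taken as fragment lengths, the fragment density behind the serum list was 12.04 times that behind the starved list. This density is the one after any scaling in peak calling, and read totals were not used. Stacked copies of single fragments would have the shortest peak length, which 96.9% of starved peaks of 1 fragment had, and 0.0% lay within 10 bp of it. This speaks only against peaks made of nothing but copies of 1 fragment. Copies joined by a few offset fragments would be longer and stay open, since the handling of duplicate reads is not given. A raised starved background held for 10.38%, so it does not account for most. A change with serum withdrawal, a weaker enrichment in the serum precipitation and another difference between 2 single library preparations stay open with 1 library per condition, untested.

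Strong serum peaks that were shared, 3195 of 3539 at a −log10 q of at least 5, may lie largely in sequence that yields many reads in precipitated and input DNA alike. A raised background was 2.1 times as frequent among them as among the unshared ones (78.7% against 37.5%), but at a −log10 q of at least 20 it held for 83.9% of 304 shared and 100% of only 11 unshared serum peaks, and for 69.0% of shared and 10.4% of unshared starved peaks. A regional trend in peak density does not account for the sharing, since moved peaks reached 16.2% of the observed overlap. Strong peaks with a low serum background were also shared in 76.0%, against 14.3% when moved. Of these 679 shared peaks, 47.0% (interval 43.2 to 50.8) overlapped a starved peak of raised background. A share under 50% had been set as the limit against a raised starved background as the explanation, and a higher limit for it. The value met the limit against it and missed the higher one. Its interval reaches past 50%, so this explanation is left open for them. Recovery of CD44-bound DNA at the same places in both conditions also stays open, untested.

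Chromosome 4 had 0.416 times the average serum peak density. A higher local background, which raises the height a peak needs, is a possible reason. Across 21 chromosomes the density fell as the share of peaks above the lowest background rose (Spearman rho −0.855), which met the limit set. Both values come from the same peaks, and each peak at the lowest background raises the density and lowers that share. A negative rho is therefore partly built in and does not decide this. Over all starved peaks the rho was −0.245 and chromosome 4 had 1.00 times the average density, while at a q of at most 0.05 it had 0.857 times and at a −log10 q of at least 5 it had 0.925 times, above chromosomes 10 (0.872) and 12 (0.798). A candidate source of this background is an extra copy of the chromosome in the cultured cells. An extra copy would add fragments to precipitated and input DNA alike, so whether it would lower the peak density stays open, untested. In both lists, 100% of the 19 windows of 10 Mb of chromosome 4 had a lower share of peaks at the lowest background than the median window of the other autosomes. This was not particular to chromosome 4: it held for 100% and 83.3% of the windows of chromosome 12 and 91.7% and 83.3% of those of chromosome 10 in the serum and starved lists, and 85.7% of those of chromosome 19 in each. The shift was largest on chromosome 4, whose median window had 4.26% of serum and 2.52% of starved peaks at the lowest background. The median windows had 15.3% and 12.2% on chromosome 12, 11.1% and 5.08% on chromosome 10, and 16.8% and 10.5% on chromosome 19. Base composition and repeat content of these chromosomes were not analysed here and stay open.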

How the results depend on the processing

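No paired analysis was possible because each condition has 1 immunoprecipitated library, and for the same reason no replicate could be left out. Leaving out unplaced sequences, Y and the mitochondrion kept 287606 serum and 403836 starved peaks. Merging could not change the totals of 289279 and 409937, since no peak overlapped another of the same list. A −log10 q of at least 5 left 3539 serum and 53117 starved peaks, and a q of at most 0.05 left 57574 and 213064. The share of serum peaks shared, 15.7% in the report, was 5.78% when 50% of both peaks had to overlap, 27.2% within 500 bp, 73.0% at −log10 q of at least 5 in both lists, 22.4% at a q of at most 0.05 in both, 13.0% with equal numbers of peaks and 9.42% at a background of up to 2 times the lowest in both. For starved peaks, 11.0% in the report, these settings gave 4.08%, 20.9%, 4.78%, 5.87%, 12.6% and 8.12%. The cause of these shifts was not tested. At −log10 q of at least 5 in both lists, 2584 of 3539 serum and 2540 of 53117 starved peaks were shared. The shares of 73.0% and 4.78% therefore differ mainly through the sizes of the lists. At this limit, 20 sets of moved peaks gave 2.87% for serum and 0.201% for starved peaks. Observed over expected overlap was 1.56 for serum and 1.52 for starved peaks with random placement, and 1.498 and 1.461 with moved peaks. Chromosome 4 in the serum list, 0.416 times the average density, stood at 0.942 at −log10 q of at least 5, at 0.424 at a q of at most 0.05 and at 0.355 at a low background. In the starved list it stood at 1.00 over all peaks and at 0.925, 0.857 and 0.687 at −log10 q of at least 5, a q of at most 0.05 and a low background. X in the serum list, 1.73 times the average, was 1.63, 1.83 and 1.79 under these settings, and in the starved list, 1.06, it was 1.111, 1.127 and 1.195. Ranking by −log10 q instead of fold left 10 of 10 serum and 4 of 10 starved peaks overlapped, against 10 and 6. The settings for q at most 0.05, low background and moved peaks were added after seeing the data. Alternatives on gene starts, annotation, gene lists and sequence were not run, because an annotation and genome of this build were not used here. In the starved list, 66.7% of peaks rest on 1 or 2 stacked fragments.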

Other observations

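All tests in this part were chosen after the data had been seen; for that of the long starved peaks, the limit was set before the value was computed. A stretch of chromosome 20 stood out in both lists by its low background. In 2 Mb windows from 12000001 to 26000000, between 73.6% and 82.8% of serum peaks and between 67.3% and 77.4% of starved peaks were at the lowest background of their list. The median 2 Mb window of the autosomes other than 20 had 20.5% in the serum and 12.5% in the starved list, and the highest of these windows had 62.1% and 47.2%. The window before the stretch had 38.1% in the serum and 28.2% in the starved list, the window after it 58.9% and 54.7%, and the next one 12.1% and 6.49%. Whether the cultured cells carried 1 copy of this segment is open: its median was 103.1% of the median of the X chromosome in the serum list and 122.8% in the starved list, but the stretch was picked by this same share, so the comparison does not decide it. Sequence to which few reads can be placed also stays open. The starved peak density in the segment was 98.3% of that on the rest of the chromosome, but starved density hardly differed between chromosomes of different background. The serum density was higher in the segment, 148.3 against 95.3 peaks per Mb on the rest (155.6%). The stretch was picked by its share of peaks at the lowest background, and each such peak also raises this density. The serum value therefore does not decide it either. A reading as 1 copy also needs cells with a single X chromosome, and the sex of the animals was not tested and is not given in the sources used here. The copy number was not measured directly, and a difference of the strain from the reference stays open.

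Long strong starved peaks were unevenly placed. Starved peaks of at least 1 kb with a −log10 q of at least 5 had a density of 7.03 per Mb on Y, from 23 peaks, 2.30 on X, 1.997 on chromosome 2, 1.86 on chromosome 11, 0.648 on chromosome 10 and 0.360 on chromosome 12. All starved peaks at that limit were 1.12 times as dense on X as on the autosomes, and the long ones 1.78 times. This distribution may reflect LINE-1 elements, repeats several kb long that are dense on the X chromosome. The value of 1.777 meets what was predicted for them, but any sequence dense on X would meet it too, so it does not single them out. The longest peaks, 6134 bp in the serum and 6689 bp in the starved list, leave LINE-1 elements open. Repeat annotation was not used here, so the elements themselves were not tested.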
